A study of Mus musculus with 16 samples.

How the data were processed

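Gene expression was measured in 4TO7 cells, a mouse mammary carcinoma line grown in 10% serum, on 16 Agilent arrays with 2 colours. Total RNA (175 ng per labelling) from cells carrying retroviral vectors was labelled with 1 dye and a universal reference RNA pooled from 11 mouse cell lines with the other. The 8 groups of 2 arrays each were cells overexpressing miRNA Cluster 1, Cluster 2, Clusters 1+2 or CDH1, and a vector control for each: Puro vector for Cluster 1, Hygro vector for Cluster 2, Hygro and Puro vectors for Clusters 1+2, and a separate Puro vector for CDH1. The miR-200 family is encoded in 2 genomic clusters, by textbook knowledge miR-200b, miR-200a and miR-429 in 1 and miR-200c and miR-141 in the other. Which of them each label means is not given in the sources used here. The sample carried Cy3 for Cluster 2, Clusters 1+2 and their controls (8 arrays) and Cy5 for Cluster 1, CDH1 and their controls (8 arrays). By the slide identifiers in the files, the 16 arrays lay on 4 slides of 4: slides 1 and 2 held repeats A and B of all Cy3 groups, slide 3 held CDH1 and its control, and slide 4 held Cluster 1 and its control. The series design calls the 2 repeats of each group biological replicates, so the p-values measure the spread between repeats, pooled over the 8 groups. Pooling assumes the same spread in all groups. Repeats lay on different slides in the Cy3 groups and on 1 slide in the Cy5 groups, so the pooled spread also holds slides. Whether the repeats were separate infections or separate cultures of 1 infected pool is not given in the sources used here. If they were cultures of 1 pool, no p-value here covers differences between independently made lines.

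Per the file headers, the deposited scanner files hold the intensity of each spot in both channels, as a spot mean and a local background median, from Agilent Feature Extraction 9.5.3.1 on array design 014868, whose probe positions follow build mm7. The authors also deposited processed intensity values, background subtracted and dye normalised by that software, and their log10 ratio of red over green per the file headers. The deposited series matrix holds 1 ratio per spot, in linear scale. It matched the processed signal of the sample over that of the reference on all 16 arrays, with a largest absolute log10 difference of 8.06e-08, and its column medians ran from 0.924 to 1.168. Direction and scale of that matrix were settled this way; whether the authors applied any further centring is not given in the sources used here, and none was detectable. All 16 matrix columns were matched to a sample, with 0 left over. The array has 45018 spots, of which 1639 are controls, and 41174 distinct probes outside the controls; 245 of them are spotted more than once. Probes were named by accession (22951), current symbol (6659) or synonym (3109), and the name in the scanner file was kept for 8455, which gave 27670 genes.

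From the scanner files, spots marked by the software as non-uniform, as population outliers, by hand, or as lying in a non-uniform local background were set missing (264 to 1493 per array). Background was then corrected with normexp (limma 3.58.1, R 4.3.3, data.table in version 1.17.8, offset 50), and each array was normalised by loess with control spots at weight 0. The log2 ratio of sample over reference was averaged over spots of a probe. A probe was kept if it was well above background in the sample channel on both arrays of at least 1 group (27089 probes), and the brightest probe stood for each gene, which left 18992 genes, 15433 of them with a gene symbol; 2820 genes lacked a value on at least 1 array. Removing marked spots before the background step was chosen after normalised values and first calls had been seen. With all spots included, a few spots far below their local background (the lowest at -56780) drove the fitted background of 5 arrays to means between -67.0 and -467.2 in the channels concerned. After removal the fitted means ran from -7.75 to 17.9. The results with those spots kept are given in the closing section.

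One limma model (lmFit and eBayes) with 8 group means was fitted over all 16 arrays, because 2 arrays per group leave few residual degrees of freedom for a comparison alone. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested; limma's moderated test is two-sided. The comparisons were each overexpression against its own control, the mean of the 3 miR-200 comparisons, 4 differences between effects, and the 2 Puro controls against each other. Overlaps are given beside the count that independent lists would share. For 25 gene lists, camera (preset inter-gene correlation 0.01) compared list members with all other genes, with adjustment over the lists of a comparison; camera with an estimated correlation and fry were run beside it, and members called were counted over all genes and adjusted over the list alone. These groups, comparisons, tests, lists and the rule for naming genes were fixed before the data were examined. Named genes were a fixed set (Cdh1, Zeb1, Zeb2, Sec23a, Igfbp4, Tinagl1, Vim, Fn1, Cdh2, Snai1, Snai2, Twist1, Epcam, Esrp1) and, per main comparison, the 10 largest rises and 10 largest falls among called genes whose overexpression arrays both lay beyond both control arrays, clone and RIKEN-type names left out. Of the differences and the control comparison the 3 largest each way were named, and of each list up to 4 called members. Any gene named outside this rule is marked as chosen after its values were seen. Where all control arrays of a gene were dim, a lower bound of its fold is given, computed from the sample channel alone at the background limit, unless it exceeds the measured fold. In gene list results, correlation-adjusted p is the adjusted p of camera with an estimated correlation.

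Genes with changes of log2 0.5, 1 and 2 added to data simulated with no other change were tested: depending on the comparison, 62.7 to 95.5% of 67 genes were called at 0.5, 94.0 to 100.0% of 67 at 1 and all 66 at 2, with 3 to 12 false calls over 18992 genes. The simulated data held no differences between slides, lines or dyes. These false calls are therefore no error level for the real comparisons. As a measure of depth, 46.4 to 69.3% of probes were well above background in the sample channel on slides 1 and 2, 50.8 to 59.3% on slide 4 and 31.2 to 64.6% on slide 3, and the number of arrays limits the precision. Other settings run were the processed signals, the series matrix, another offset (10), median centring, scaled spread, the sample channel alone, other filters, the mean of all probes, only the arrays compared, a mean-variance trend, array weights, a replicate block, a slide block, and leaving out each array. The arrays were first processed with marked spots kept in the background fit, which is now an added alternative (outlier spots kept). The other Puro vector as control of CDH1 or of Cluster 1 was also added after seeing the data. A test of miR-200 seed sites in 3' UTRs was not run, since transcript sequences were not used here. No array was left out.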

Results

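Expression of 18992 genes was compared in 16 arrays of 4TO7 cells, with 2 arrays per group. Repeats of a group differed by a median of 0.0827 to 0.108 in absolute log2 ratio and correlated at 0.938 to 0.981 across genes, which are not independent replicates. Values below are log2 fold changes against the matched vector control with their standard error (SE) and adjusted p from limma. They set 2 arrays against 2, or fewer where a marked spot was missing, as for Vim in Cluster 2. Each gene given as a largest rise or fall lay beyond both control arrays on both overexpression arrays.

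Cdh1, which encodes the epithelial adhesion protein E-cadherin, was examined first, in every sample. Its log2 ratio to the reference was 1.01 and 0.94 in the Hygro vector arrays and 3.06 and 2.76 in Cluster 2. It was 1.39 and 1.08 with Hygro and Puro vectors and 4.22 and 3.96 in Clusters 1+2. In the Puro vector for Cluster 1 it was -0.01 and 0.09, and in Cluster 1 1.21 and 1.29. The Puro vector for CDH1 gave 0.03 and 0.09, not above background on either array, and the CDH1 cells 0.57 and 0.77. These ratios compare only with the matched control, since dye and slides differ between the Cy3 and Cy5 groups. Cdh1 therefore rose by 1.21 in Cluster 1 (SE 0.126, adjusted p = 9.49e-05), 1.93 in Cluster 2 (adjusted p = 2.88e-06) and 2.86 in Clusters 1+2 (adjusted p = 8.76e-09). In CDH1 cells Cdh1 was called higher, with a difference of 0.61 (SE 0.126, adjusted p = 0.00569). The control lay at background, so 0.61 is no measured size of the rise. That value rests on 1 probe (A_51_P137336, chromosome 8, 105268557 to 105268616, build mm7). Whether the probe lies within the introduced CDH1 sequence, and the species of that sequence, are not given in the sources used here. Without CDH1 replicate B the call ended (log2 fold change 0.51, adjusted p = 0.0696). The processed signals of the scanner software gave 2.53 (adjusted p = 0.000794) in CDH1 and 2.41 (adjusted p = 0.00176) in Cluster 1. Those signals differ in background and normalisation together, while offset 10 alone gave 1.20 in CDH1 and 1.80 in Cluster 1. With outlier spots kept in the background fit neither call held (Cluster 1 0.82, adjusted p = 0.623; CDH1 0.56, adjusted p = 0.44).

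**Figure D1:**
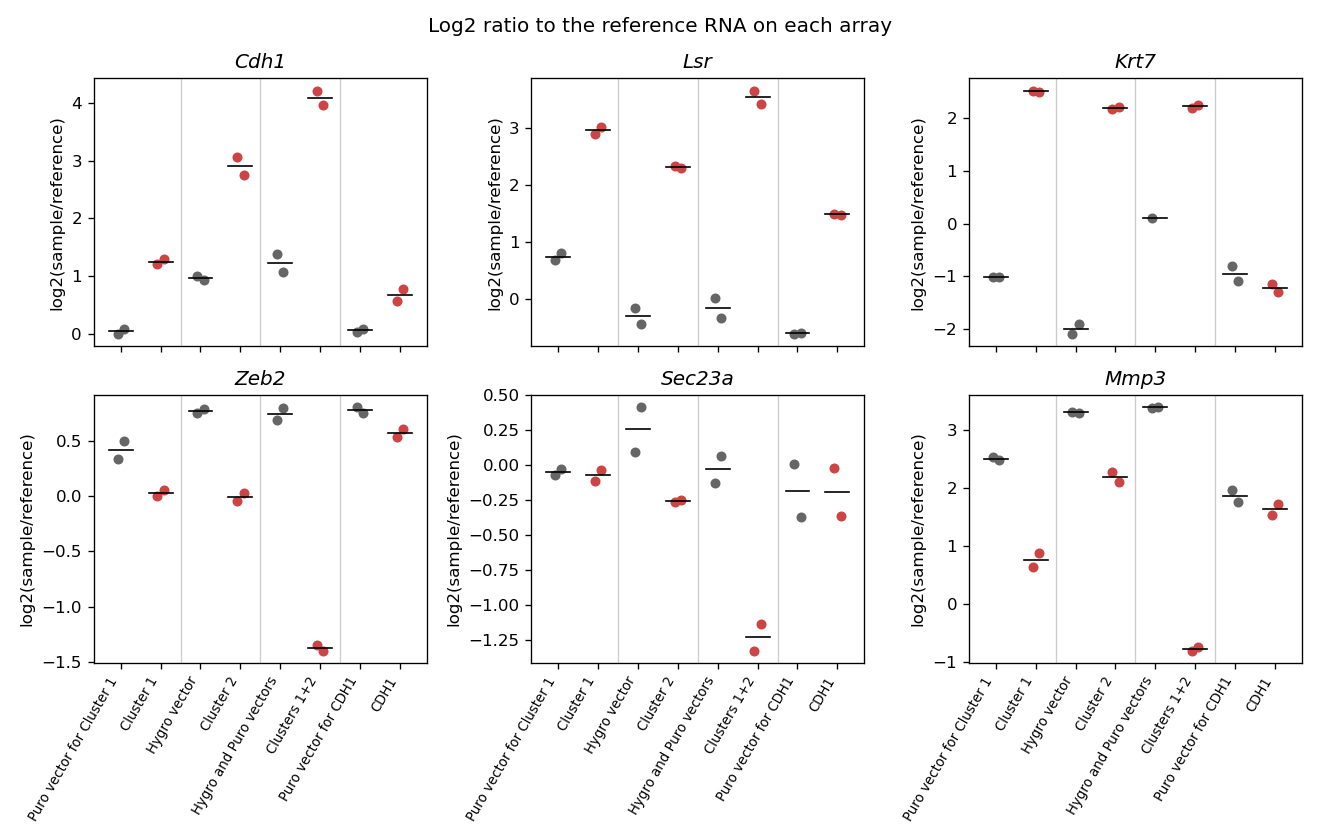
Log2 ratio of sample over reference on each of the 16 arrays for Cdh1, Lsr, Krt7, Zeb2, Sec23a and Mmp3, in grey for vector controls and red for overexpression, with a line at each group mean. Cdh1 reaches 4.22 and 3.96 in Clusters 1+2, against 1.39 and 1.08 in its control. Levels compare only with the matched control, since dye and slides differ between the Cy3 and Cy5 groups.

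The first comparison asked what Cluster 1 changes relative to its Puro vector. Krt7, a keratin of simple epithelia, rose by 3.52 (SE 0.101, adjusted p = 1.22e-08), 11.5-fold. Lsr, a component of tricellular junctions, rose by 2.22 (SE 0.121, adjusted p = 5.39e-07), and Perp, a desmosomal protein, by 1.94 (SE 0.0695, adjusted p = 1.46e-08). Mmp3, a matrix metalloprotease, fell by 1.74 (SE 0.0996, adjusted p = 7.52e-07), and the prolactin family gene Prl2c5 fell by 1.56 (SE 0.0885, adjusted p = 7.52e-07). The other largest rises were Grb7 (1.88), Rhpn2 (1.85), Paox (1.81), Msln (1.78), Shtn1 (1.70), the complement gene C3 (1.69) and Rdm1 (1.64). The other largest falls were Prl2c3 (-1.48), the cytokine gene Il11 (-1.26), Pakap (-1.10), Col9a1 (-1.04), Apcdd1 (-1.01), Bok (-0.95), Sema6d (-0.95) and Atp2c2 (-0.88). Epcam, an epithelial adhesion gene, rose by 1.40 (SE 0.167, adjusted p = 0.000263). Zeb2, a repressor of Cdh1 and a miR-200 target, fell by 0.39 (SE 0.074, adjusted p = 0.0059), and Tinagl1 fell by 0.38 (SE 0.0915, adjusted p = 0.0222). Zeb1 (0.26, adjusted p = 0.616), Sec23a (-0.03, adjusted p = 0.961), Igfbp4 (-0.20, adjusted p = 0.392), Vim (-0.38, adjusted p = 0.132), Fn1 (0.14, adjusted p = 0.541), Snai1 (-0.08, adjusted p = 0.757), Snai2 (0.30, adjusted p = 0.807), Twist1 (0.08, adjusted p = 0.918) and Esrp1 (-0.12, adjusted p = 0.53) were not called. Twist1 and Esrp1 were dim on all 4 arrays. Cdh2 was not tested in any comparison, since no group had it above background on both arrays. Against the Puro vector for CDH1, on slide 3, a comparison chosen after seeing the data, Krt7 (3.46), Lsr (3.57), Perp (3.17), Epcam (1.62) and Zeb2 (-0.75) were called in the same direction in Cluster 1. For Cdh1 and Grb7 that control was not above background on either array, so no size is given. C3 (0.12, adjusted p = 0.481), Col9a1 (-0.01, adjusted p = 0.995) and Tinagl1 (-0.10, adjusted p = 0.672) were not called against it. Smaller there were Rdm1 (0.83), Mmp3 (-1.10), Prl2c5 (-0.63), Prl2c3 (-0.65), Il11 (-0.28, adjusted p = 0.0425) and Bok (-0.50). Fn1 turned to -0.77 (adjusted p = 0.000469). The other largest rises and falls kept their direction and call.

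Among 47 measured epithelial genes, 12 rose and none fell in Cluster 1 (18 and 0 adjusted over the list alone), with a mean log2 fold change of 0.462 (camera adjusted p = 4.85e-25, and correlation-adjusted p = 0.015). Of 25 cholesterol synthesis genes 17 rose (19 adjusted over the list alone; camera adjusted p = 9.92e-18, correlation-adjusted p = 0.015), among them Tm7sf2 (0.96), Insig1 (0.67) and Idi1 (0.58). Members of the adherens junction complex rose in 5 of 18 cases (9 adjusted over the list alone), including Nectin2 (0.75), Ctnnb1 (0.54) and Ajuba (0.52). The camera adjusted p was 5.88e-06, and the correlation-adjusted p = 0.0177. Interferon-stimulated genes rose in 13 of 34 cases (17 adjusted over the list alone), with Ifi27 at 1.08, Isg20 at 1.08, Psmb9 at 1.07 and Psmb8 at 1.05 (camera adjusted p = 1.53e-21, correlation-adjusted p = 0.0454). Of 42 cell cycle genes 7 fell and none rose (14 fell and 1 rose adjusted over the list alone), with Ccne2 at -0.56 and Mcm5 at -0.49 (camera adjusted p = 0.000178, correlation-adjusted p = 0.032). Among 53 reported miR-200 targets 6 fell and 2 rose, the same counts adjusted over the list alone. Flt1 (-0.71) and Ppm1f (-0.63) fell, and Rnd3 (0.68) and Ctnnb1 rose (camera adjusted p = 0.0406, correlation-adjusted p = 0.116). Collagens and matrix glycoproteins counted 9 higher and 1 lower of 39 (10 and 2 adjusted over the list alone), with Mgp at 1.53 and Col7a1 at 1.05 (camera adjusted p = 4.25e-06, correlation-adjusted p = 0.247). Among 28 unfolded protein response genes 8 rose (9 adjusted over the list alone), including Trib3 (0.69), with camera adjusted p = 1.37e-05 and correlation-adjusted p = 0.225. Mesenchymal genes showed 1 lower of 26 (camera adjusted p = 0.822). The mean of that list was 0.0351 although its test pointed down. It was negative under scaled spread (-0.115), the processed signals (-0.128) and the sample channel alone (-0.122). Some of these list results depended on the control. Against the Puro vector for CDH1, interferon-stimulated genes had 2 higher and 4 lower (mean -0.0412), cell cycle genes 4 and 2 (mean 0.0375), unfolded protein response genes 2 and 6 (mean -0.0514) and collagens 6 and 5 (mean 0.0232, though the test pointed down), with camera adjusted p from 0.187 to 0.75. Epithelial genes had 14 higher and 1 lower (correlation-adjusted p = 0.0363) and adherens junction genes 6 higher (correlation-adjusted p = 0.0363). Cholesterol synthesis genes had 9 higher (camera adjusted p = 4.85e-08, correlation-adjusted p = 0.0608). Reported miR-200 targets had 3 higher and 10 lower (correlation-adjusted p = 0.166) and mesenchymal genes 1 and 5 (mean -0.223, camera adjusted p = 0.00184, correlation-adjusted p = 0.728).

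In all, 1560 of 18973 genes were called in Cluster 1, 921 higher and 639 lower, of which 51 and 9 changed at least 2-fold. All 4 arrays lay on slide 4. Against the Puro vector for CDH1 1628 genes were called, of which 543 changed the same way against both controls and 69 the opposite way (correlation of 0.441 across genes, beside 0.475 in simulated data with no change, where the Cluster 1 arrays are shared). The split was 395 higher and 173 lower with the processed signals and 782 and 345 under median centring. Only 195 genes were called with outlier spots kept (the calls of Perp, Grb7, Rhpn2, Prl2c3, Col9a1, Apcdd1, Sema6d, Atp2c2, Zeb2, Tinagl1 and Epcam ended). Leaving out 1 array gave 675 without Cluster 1 replicate A, 978 without replicate B, and 834 or 841 without replicate A or B of the control. The Zeb2 call ended without Cluster 1 replicate A (adjusted p = 0.0607) or without replicate B of its control (adjusted p = 0.066). The Col9a1 call ended on leaving out any of the 4 arrays, and Pakap had a mean over its probes of -0.275 (adjusted p = 0.0893).

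**Figure D2:**
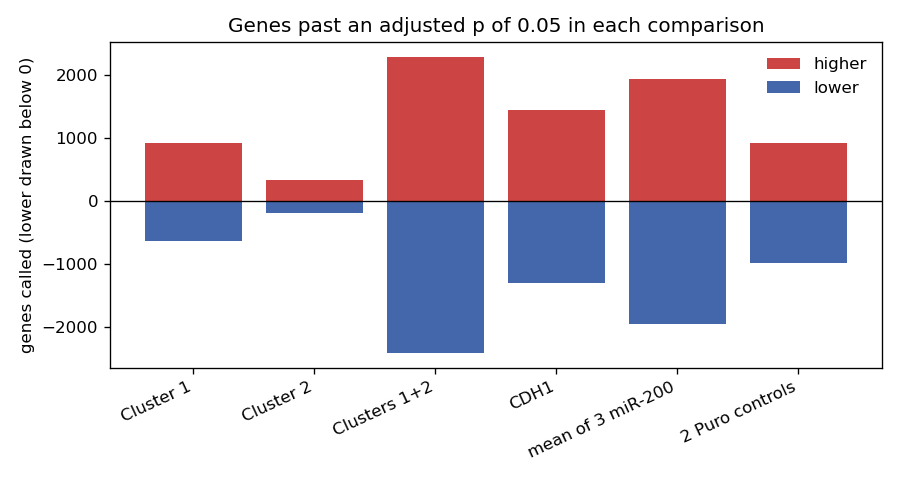
Number of genes called at an adjusted p under 0.05, higher above 0 and lower below 0, for the 4 overexpressions, the mean of the 3 miR-200 overexpressions and the 2 Puro controls. Clusters 1+2 has 2281 higher and 2418 lower, and Cluster 2 324 and 197.

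Cluster 2 was compared with the Hygro vector on slides 1 and 2, with 1 array of each group per slide. Krt7 rose by 4.19 (SE 0.101, adjusted p = 1.71e-09; 4.27 on slide 1 and 4.11 on slide 2). Lsr rose by 2.62 (SE 0.121, adjusted p = 1.32e-07), Mpzl2, a junctional adhesion gene, by 2.56 (SE 0.113, adjusted p = 9.37e-08), and the potassium channel tetramerisation gene Kctd12b by 2.75 (SE 0.152, adjusted p = 7.15e-07; 3.09 on slide 1 and 2.41 on slide 2). Serpinb5, the epithelial serpin maspin, was at least 5.35-fold higher (adjusted p = 6.73e-06), and Crb3, a polarity gene, at least 2.74-fold higher (adjusted p = 9.37e-08), since both controls were dim for each. Il33, an alarmin cytokine, fell by 1.51 (SE 0.115, adjusted p = 8.46e-06; -1.67 and -1.36 by slide). Prnd (2.21), Hs3st1 (2.18), Perp (1.96) and Cdh1 (1.93; 2.05 on slide 1 and 1.82 on slide 2) completed the largest rises. Lgi2 (-1.20), Mmp3 (-1.12), Vcam1 (-1.06), Aqp1 (-1.03), Cebpd (-0.99), Gbp7 (-0.94), Selenbp1 (-0.91), Ifi202b (-0.85) and Selenbp2 (-0.83) completed the falls. Zeb2 fell by 0.77 (SE 0.074, adjusted p = 6.85e-05), and Epcam rose by 1.67 (SE 0.167, adjusted p = 9.62e-05). Sec23a, a COPII coat gene, was at -0.51 (SE 0.145, adjusted p = 0.0954) and was not called, though it was lower on both slides (-0.359 on slide 1 and -0.663 on slide 2). Also not called were Zeb1 (-0.32, adjusted p = 0.544), Igfbp4 (-0.22, adjusted p = 0.39), Tinagl1 (-0.01, adjusted p = 0.976), Vim (-0.33, adjusted p = 0.401), Fn1 (-0.18, adjusted p = 0.438), Snai1 (-0.01, adjusted p = 0.969), Snai2 (-0.35, adjusted p = 0.789), Twist1 (-0.46, adjusted p = 0.383) and Esrp1 (0.06, adjusted p = 0.827).

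Epithelial genes rose in 18 of 47 cases in Cluster 2 and fell in none (22 and 0 adjusted over the list alone). Their mean was 0.679 on slide 1 and 0.611 on slide 2 (camera adjusted p = 7.16e-68, correlation-adjusted p = 0.00146). Of the cholesterol synthesis genes 8 of 25 rose (16 adjusted over the list alone), including Idi1 (0.64), Dhcr7 (0.54) and Hmgcs1 (0.45), with slide means of 0.25 and 0.275 (camera adjusted p = 1.4e-13, correlation-adjusted p = 0.0106). Adherens junction genes rose in 3 of 18 cases (4 adjusted over the list alone), with Ajuba at 0.69 and Jup at 0.37 (camera adjusted p = 3.63e-06, correlation-adjusted p = 0.0441). Among 52 measured reported miR-200 targets 5 fell and 1 rose (12 and 2 adjusted over the list alone; camera adjusted p = 0.000734, correlation-adjusted p = 0.0248), with a mean of -0.104 that turned to 0.0847 under median centring. Flt1 (-0.79) and Reck (-0.55) fell and Jag1 (1.07) rose. Interferon-stimulated genes counted 7 lower and 1 higher of 34 (13 and 1 adjusted over the list alone), with Ifit1 at -0.69 and Oasl2 at -0.63, Isg20 being the member that rose (0.88; camera adjusted p = 2.73e-07, correlation-adjusted p = 0.222). In the mesenchymal list 2 of 26 fell, Zeb2 and Pdgfra (-0.60), and 3 adjusted over the list alone (camera adjusted p = 2e-04, correlation-adjusted p = 0.5; slide means -0.363 and -0.107). Collagens and matrix glycoproteins rose in 8 of 39 cases, with Lamb3 at 1.49 and Col7a1 at 1.45, although the list median was -0.0939 and the mean of 0.0823 turned to -0.154 with outlier spots kept (camera adjusted p = 0.0095, correlation-adjusted p = 0.59). Of 42 cell cycle genes limma called 0, also when adjusted over the list alone (camera adjusted p = 0.46). The mean of -0.0274 turned to 0.266 under median centring.

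Cluster 2 gave 521 called genes of 18944, 324 higher and 197 lower, 62 and 5 of them at least 2-fold. The 2 Puro controls, alike by their labels but on different slides, differed in 1903 genes, more than the 1560 of Cluster 1. No second control with the same vectors was measured for Cluster 2 or Clusters 1+2, so their calls could not be checked that way. The changes of all genes in Cluster 2 correlated at 0.466 between slides. With the slide as a block 784 were called in Cluster 2 (431 higher, 353 lower). Under other scalings the split was 82 higher and 7 lower (processed signals), 2122 and 150 (median centring), 67 and 8 (scaled spread) or 152 and 57 (sample channel alone). The count was 805 without Hygro vector replicate A, where the balance turned to 289 higher and 516 lower, 231 without its replicate B and 297 without Cluster 2 replicate B. Scaled spread ended the calls of Mmp3, Vcam1, Aqp1, Cebpd, Selenbp1, Selenbp2, Ifi202b, Prnd and Epcam. The processed signals ended those of Prnd, Lgi2, Gbp7, Ifi202b, Selenbp2, Zeb2 and Epcam, and keeping outlier spots those of Mpzl2, Prnd, Perp, Vcam1, Selenbp1, Selenbp2, Zeb2 and Epcam. Ifi202b was also lost without Hygro vector replicate B (adjusted p = 0.0659).

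Clusters 1+2 were compared with the Hygro and Puro vectors on the same pair of slides. Mpzl2 rose by 4.16 (SE 0.113, adjusted p = 2.27e-10), Lsr by 3.71 (SE 0.121, adjusted p = 9.68e-10) and Crb3 by 3.63 (SE 0.0851, adjusted p = 7.6e-11). The desmosome gene Dsp rose by 3.18 (SE 0.0969, adjusted p = 5.48e-10) and Epcam by 3.23 (SE 0.167, adjusted p = 3.08e-08). Mmp3 fell by 4.16 (SE 0.0996, adjusted p = 7.6e-11), and the adhesion receptor gene Adgrg1 fell by 3.20 (SE 0.101, adjusted p = 2.13e-09). Zeb2 fell by 2.10 (SE 0.074, adjusted p = 1.7e-09), and by 2.27 (0.98 in Cluster 1) on its other probe above background on all 16 arrays. Dimmer probes ranged from 0.18 to -1.185. Sec23a fell by 1.20 (SE 0.145, adjusted p = 4.97e-05). Of the genes listed as Sec23a-dependent secreted factors, Igfbp4 mRNA fell by 1.07 (SE 0.113, adjusted p = 1.64e-05) and Tinagl1 mRNA fell by 0.37 (SE 0.0915, adjusted p = 0.00968). Secretion was not measured, and a link of these mRNA changes to Sec23a was not tested. Vim, a mesenchymal intermediate filament, fell by 0.87 (SE 0.136, adjusted p = 0.000567), and Snai1, a further Cdh1 repressor, fell by 0.58 (SE 0.0893, adjusted p = 0.000358). Esrp1, an epithelial splicing regulator, was above background only in this group, at least 1.83-fold higher (adjusted p = 1.98e-07). Kctd12b (4.18), Grb7 (3.59), Serpinb5 (3.54), Kcnk1 (3.34) and Lamb3 (3.09) were the other largest rises. Slc14a1 (-2.90), Mgp (-2.75), Il33 (-2.58), Casp1 (-2.54), Galnt15 (-2.52), Selenbp1 (-2.39) and Medag (-2.37) were the other falls. Col9a1 was at least 4.14-fold lower. Krt7 was at 2.11 on the probe used, where 1 control array was missing, and at 4.08 on its second probe. Twist1 was at -0.72 (adjusted p = 0.0362), a call that ended with no filter, with scaled spread and with the processed signals. Zeb1 (0.00, adjusted p = 0.996), Fn1 (-0.21, adjusted p = 0.157) and Snai2 (0.01, adjusted p = 0.995) were not called.

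Of 47 epithelial genes 33 rose and 1 fell in Clusters 1+2 (34 and 1 adjusted over the list alone; camera adjusted p = 4.5e-48, correlation-adjusted p = 0.00121), with slide means of 1.2 and 1.07. Cholesterol synthesis genes rose in 24 of 25 cases, also adjusted over the list alone, with Idi1 at 2.41, Hmgcs1 at 1.89 and Msmo1 at 1.88 (camera adjusted p = 3e-70, correlation-adjusted p = 0.00121). Reported miR-200 targets fell in 23 of 53 cases and rose in 6 (23 and 7 adjusted over the list alone). Flt1 (-2.34) and Qk (-1.71) fell, Jag1 (1.83) rose, and the list mean was -0.253 on slide 1 and -0.259 on slide 2 (camera adjusted p = 1.47e-06, correlation-adjusted p = 0.0123). In the mesenchymal list 8 of 26 fell and 1 rose, also adjusted over the list alone, with S100a4 at -1.71 and Pdgfra at -1.69 (camera adjusted p = 0.000644, correlation-adjusted p = 0.688). Adherens junction genes counted 9 higher and 1 lower of 18, also adjusted over the list alone, with Ajuba at 1.46, Plekha7 at 0.87 and Nectin2 at 0.80 (camera adjusted p = 6.19e-05, correlation-adjusted p = 0.0537). Both Sec23a-dependent secreted factors fell (camera adjusted p = 0.0348, correlation-adjusted p = 0.266), whereas the 36 genes of COPII and the early secretory pathway had 5 lower and 2 higher (camera adjusted p = 0.267), with Sec24d at -0.41 and Uso1 at 0.40. Collagens and matrix glycoproteins moved both ways, 8 higher and 10 lower of 39, as with Lamb3 against Mgp and Col6a3 (-2.25; camera adjusted p = 0.839). Cell cycle genes showed 3 higher and 8 lower of 42 (camera adjusted p = 0.49), and interferon-stimulated genes 12 higher and 4 lower of 34, with Isg20 at 1.66 and Ifih1 at 0.69 (camera adjusted p = 0.0445, correlation-adjusted p = 0.625).

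Clusters 1+2 gave 4699 called genes of 18961, 2281 higher and 2418 lower, 266 and 208 of them at least 2-fold. The changes correlated at 0.838 between slides across genes. With the processed signals the split was 591 higher and 997 lower, scaled spread left 1853 genes called and the sample channel alone 2698. The Igfbp4 and Tinagl1 calls ended with the processed signals, and that of Tinagl1 also under scaled spread and with outlier spots kept.

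**Figure D3:**
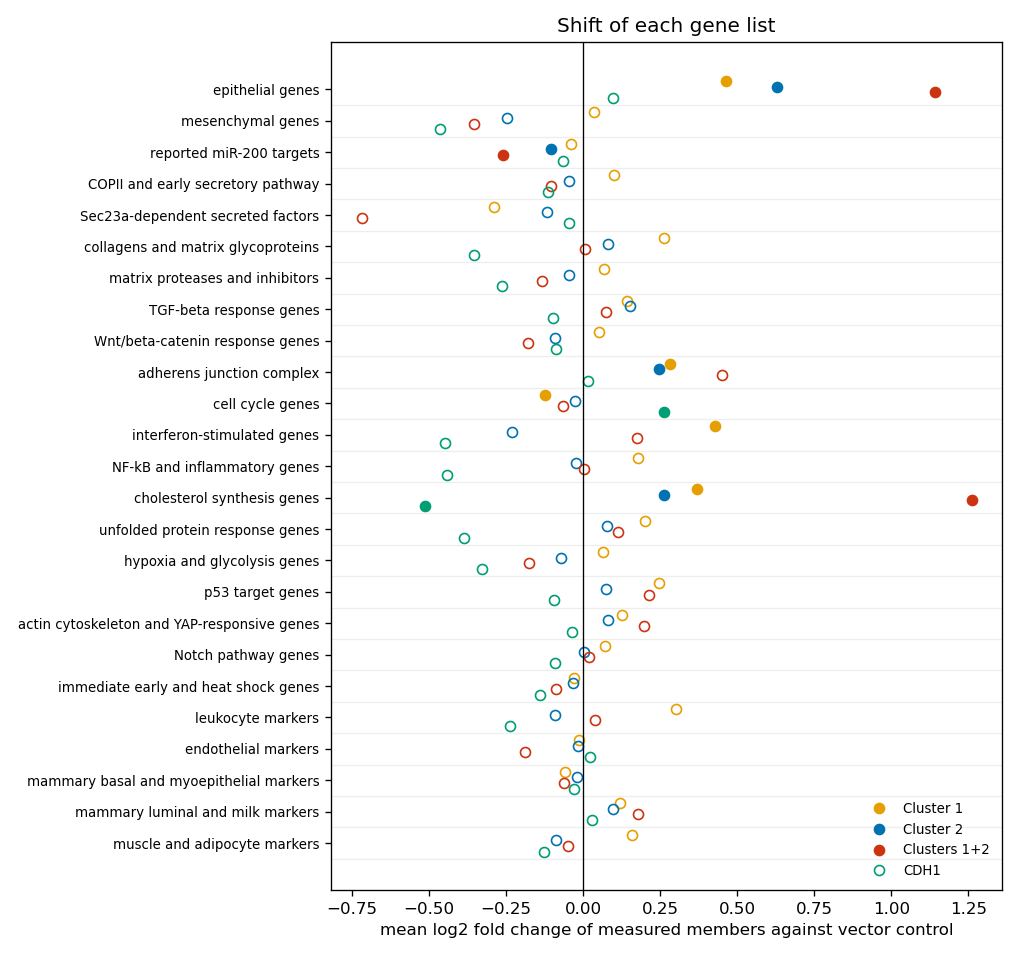
Mean log2 fold change of the 25 gene lists in the 4 overexpression comparisons, with filled points where the correlation-adjusted p was under 0.05. Cholesterol synthesis genes lie at 1.26 in Clusters 1+2 and at -0.513 in CDH1.

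Cells overexpressing CDH1 were compared with their own Puro vector, all on slide 3, which asks what E-cadherin alone changes. Perp rose by 2.20 (SE 0.0695, adjusted p = 6.39e-09), Lsr by 2.10 (SE 0.121, adjusted p = 4.49e-07) and Shtn1, a neuronal polarity gene, by 1.93 (SE 0.0774, adjusted p = 1.43e-08). Emilin2, an extracellular matrix glycoprotein, fell by 2.98 (SE 0.105, adjusted p = 1.03e-08), and Cebpd, a transcription factor of the acute phase response, fell by 2.40 (SE 0.102, adjusted p = 2.27e-08). Against the other Puro vector, on slide 4, Perp was at 0.97 (adjusted p = 3.85e-05), Lsr at 0.74 (adjusted p = 0.00831), Shtn1 at 1.06, Emilin2 at -0.47 (adjusted p = 0.0367) and Cebpd at -1.25 (adjusted p = 7.15e-05). The other rises against the own control were Id2 (1.55), Kctd12b (1.43), Ggct (1.19), Prl2c5 (1.16), Fzd6 (1.14), Plscr2 (1.14) and Prnd (1.53), whose control was dim. Of these Id2 (0.68), Kctd12b (1.17), Ggct (0.54) and Prnd (1.11) were also called against the other control. Prl2c5 (0.23, adjusted p = 0.243), Fzd6 (0.30, adjusted p = 0.0838) and Plscr2 (0.34, adjusted p = 0.214) were not called against it. Among the falls, Fgf7 (-2.15), Pla2g5 (-2.13), C3 (-2.05), Ugt1a6b (-1.83) and Ccl2 (-1.78) were lower against the other control too (-0.58, -0.37, -0.48, -0.88 and -0.45). Hp (-2.04), Cyp26b1 (-1.93) and Krt76 (-1.80) were not called against it (0.07, -0.16 and -0.19). Fn1, the matrix glycoprotein fibronectin, fell by 1.13 (SE 0.101, adjusted p = 1.38e-05), with its probes at -1.13, -0.73 and -0.06, and was at -0.22 (adjusted p = 0.347) against the other control. Zeb2 (-0.21, adjusted p = 0.0817), Zeb1 (-0.41, adjusted p = 0.277), Sec23a (-0.01, adjusted p = 0.975), Igfbp4 (-0.27, adjusted p = 0.147), Tinagl1 (0.18, adjusted p = 0.242), Vim (-0.30, adjusted p = 0.187), Snai1 (-0.12, adjusted p = 0.44), Snai2 (-0.41, adjusted p = 0.633), Twist1 (-0.31, adjusted p = 0.456), Epcam (-0.44, adjusted p = 0.105) and Esrp1 (0.01, adjusted p = 0.971) were not called.

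Cholesterol synthesis genes fell in 20 of 25 cases in CDH1 and rose in none, also adjusted over the list alone, with Sqle at -1.18, Srebf2 at -1.16, Hmgcs1 at -1.02 and Fdps at -0.97 (camera adjusted p = 6.39e-24, correlation-adjusted p = 0.0103). Against the other control 14 were lower and 1 higher, with a mean of -0.412. Cell cycle genes rose in 18 of 42 cases and fell in 1 (25 and 1 adjusted over the list alone), including Mcm2 (0.75), Tyms (0.68), Ccne2 (0.65) and Ccne1 (0.63; camera adjusted p = 1.27e-09, correlation-adjusted p = 0.00973). Of the interferon-stimulated genes 14 of 34 fell (20 adjusted over the list alone), led by Ifi202b (-1.73) and Psmb8 (-1.50), with a mean of -0.448 that was 0.0203 against the other control (camera adjusted p = 2.69e-16, correlation-adjusted p = 0.102). Among 27 NF-kB and inflammatory genes 13 fell and 3 rose (14 and 3 adjusted over the list alone), with Cxcl5 at -1.62 and Ccl7 at -1.47 (camera adjusted p = 7.67e-11, correlation-adjusted p = 0.102). Unfolded protein response genes fell in 17 of 28 cases (21 lower and 1 higher adjusted over the list alone), with Creld2 at -0.90 and Pdia6 at -0.84 (camera adjusted p = 1.1e-13, correlation-adjusted p = 0.102). Hypoxia and glycolysis genes counted 12 lower and 1 higher of 31 (15 and 2 adjusted over the list alone), with Aldoc at -1.47 and Ddit4 at -1.41 (camera adjusted p = 1.47e-08, correlation-adjusted p = 0.175). In the mesenchymal list 7 of 26 fell and 2 rose (9 and 2 adjusted over the list alone), with S100a4 at -1.46, Pdgfra at -1.07 and Sparc at -0.99 (camera adjusted p = 9.31e-06, correlation-adjusted p = 0.357). Collagens and matrix glycoproteins fell in 13 of 39 cases (14 lower and 1 higher adjusted over the list alone), with Mgp at -1.57 and Col5a1 at -1.05 (camera adjusted p = 8.88e-08, correlation-adjusted p = 0.181). Epithelial genes went both ways, 7 higher and 4 lower of 47 (7 and 5 adjusted over the list alone; camera adjusted p = 0.0352, correlation-adjusted p = 0.666), but 5 were higher and none lower against the other control (mean 0.0854, camera adjusted p = 0.0131, correlation-adjusted p = 0.412). Reported miR-200 targets had 4 higher and 8 lower of 53 (camera adjusted p = 0.33). Against the other control 1 cell cycle gene was higher (mean 0.10, correlation-adjusted p = 0.105), 1 unfolded protein response gene lower (mean -0.133) and 4 NF-kB genes lower and 1 higher (mean -0.113). Lower there were also 4 hypoxia genes, 1 mesenchymal gene and 2 collagens, and only the cholesterol list kept its call with an estimated correlation (0.00677).

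CDH1 gave 2750 called genes of 18983, 1446 higher and 1304 lower, 24 and 101 of them at least 2-fold. Against the other Puro vector, an alternative chosen after seeing the data, 458 were called (239 higher, 219 lower), of which 284 changed the same way against both controls and 14 the opposite way. The changes against both correlated at 0.498 across genes, beside 0.486 in simulated data with no change, since the CDH1 arrays are shared. The split was 1065 higher and 556 lower with the processed signals, where the median of all genes shifted to 0.151. It was 3126 and 664 under median centring, with a median of 0.105, and in Cluster 2 median centring moved that median to 0.135. With outlier spots kept 1255 genes were called and the calls of Perp, Prnd, Kctd12b, Hp and Krt76 ended. Without CDH1 replicate B 1542 genes were called (720 higher, 822 lower), and 1746 (835 and 911) without replicate B of its control, the array with the fewest probes above background (31.2%).

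**Figure D4:**
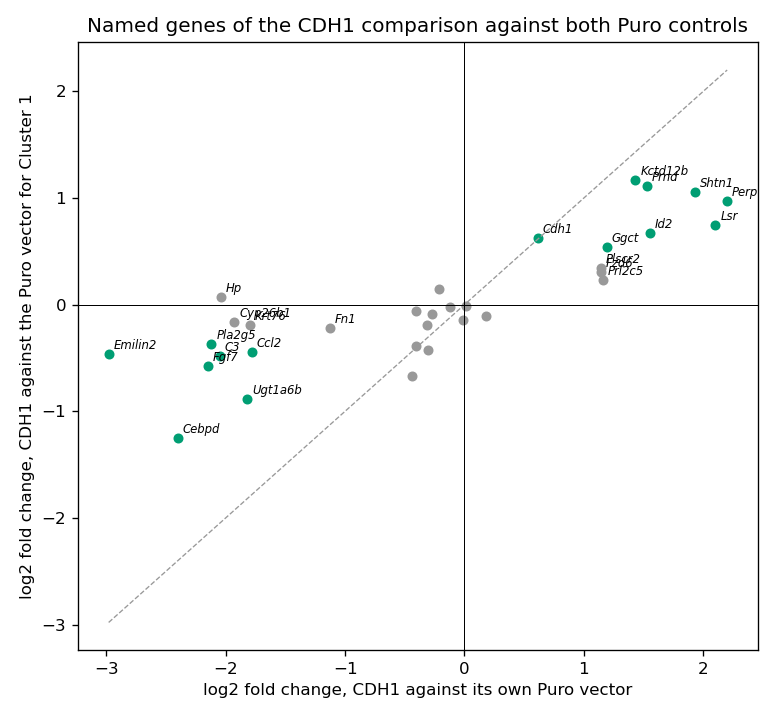
Log2 fold change of named genes in CDH1 against its own Puro vector (horizontal) and against the Puro vector for Cluster 1 (vertical), green where the adjusted p against the other control was under 0.05, with a dashed line of equal values. Hp lies at -2.04 and 0.07, and Cebpd at -2.40 and -1.25.

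The mean of the 3 miR-200 comparisons gave their average change, with 6 arrays against 6, which Clusters 1+2 alone can carry. Krt7 (3.28, SE 0.0628, adjusted p = 4.46e-11), Lsr (2.85, SE 0.07, adjusted p = 5.01e-11) and Perp (2.26, SE 0.0401, adjusted p = 5.36e-12) rose, as did Mpzl2 (2.65), Kctd12b (2.43), Grb7 (2.41), Serpinb5 (2.32), Gsn (2.18), Epcam (2.10), Msln (2.02) and Cdh1 (2.00, SE 0.073). The Serpinb5 value and the Col9a1 value below are no exact sizes, since Serpinb5 in Cluster 2 and Col9a1 in Clusters 1+2 were only bounded. Mmp3 fell by 2.34 (SE 0.0575, adjusted p = 5.01e-11) and Zeb2 fell by 1.09 (SE 0.0428, adjusted p = 3.31e-09). Further falls were Col9a1 (-1.32), the inflammatory caspase gene Casp1 (-1.31), Flt1 (-1.28), Slc14a1 (-1.24), Phex (-1.22), Medag (-1.17), the leukocyte adhesion gene Vcam1 (-1.14) and Galnt15 (-1.11). Of these Kctd12b, Col9a1, Slc14a1 and Galnt15 were not called in all 3 comparisons. With Cluster 1 taken against the other Puro vector these 4 stayed called in the mean, Col9a1 at -0.97 and Slc14a1 at -0.85, while Gsn was at 1.75. Sec23a fell by 0.58 (SE 0.0837, adjusted p = 0.000262), with its value in Clusters 1+2 alone called among the 3 comparisons. Epithelial genes rose in 33 of 47 cases and fell in 1 (37 and 1 adjusted over the list alone), cholesterol synthesis genes rose in 24 of 25, and reported miR-200 targets fell in 22 of 52 and rose in 5 (camera adjusted p = 1.86e-06, correlation-adjusted p = 0.0106). Cell cycle genes had 2 higher and 12 lower of 42 and a mean of -0.0723 that turned to 0.023 under median centring (camera adjusted p = 0.0499, correlation-adjusted p = 0.093; 0.641 by camera with the other Puro vector for Cluster 1). In all 3898 of 18909 genes were called, 1941 higher and 1957 lower (2254 and 979 under median centring), 79 and 21 of them at least 2-fold.

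Called genes overlapped between the miR-200 comparisons. Cluster 1 and Cluster 2 shared 179 higher and 39 lower genes, against 15.7 and 6.63 for independent lists, and 28 genes changed in opposite directions. Cluster 2 and Clusters 1+2 shared 298 higher and 175 lower genes (38.9 and 25.1 for independent lists) and 1 opposite, with a correlation of 0.588 across genes. Cluster 1 and Clusters 1+2 shared 421 higher and 249 lower genes (111 and 81.4 for independent lists) and 214 opposite, with a correlation of 0.297. All 3 miR-200 comparisons called 169 genes higher and 39 lower, against 1.89 and 0.844 for independent lists. Among those higher were Krt8 and Krt18, keratins of simple epithelia, the integrin gene Itgb4 and the actin severing gene Gsn, and among those lower Flt1, Vcam1, Casp1 and Jun, examples chosen after their values were seen. Of the 169, 35 were also higher and 51 lower in CDH1, and of the 39, 12 were also lower and 9 higher. With CDH1 taken against the other Puro vector 33 of the 169 were higher and 11 lower, and 10 of the 39 were lower and 1 higher. With Cluster 1 against the other Puro vector 111 of the 169 were higher and 7 lower there, and 26 of the 39 were lower and 1 higher. Gsn (0.24, adjusted p = 0.072) and Flt1 (-0.21, adjusted p = 0.0772) were not called in that comparison. CDH1 shared 453 higher and 463 lower genes with Clusters 1+2 (174 and 166 for independent lists), with 481 opposite, and 61 and 80 with Cluster 2 (24.7 and 13.5), with 88 opposite. With Cluster 1 it shared 71 higher and 33 lower genes (70.1 and 43.9 for independent lists) and 712 opposite, and the changes of all genes correlated at -0.385. Genes are not independent replicates, so no p is given for these correlations.

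Effects were then compared. Ratio spread differed between arrays along with dye, slides and reference signal. The slope of a ratio on the mean ratio over all arrays was 0.673 to 0.812 for Cluster 1 and its control, 0.678 to 0.907 for CDH1 and its control (all Cy5) and 1.16 to 1.35 for the Cy3 groups. Effects in the Cy3 groups thus lay on a wider scale than those in the Cy5 groups. Median reference signals ran from 155.2 to 216.6 on slides 1 and 2 and from 33.44 to 46.52 on slides 3 and 4. Dye, slides and reference signal cannot be told apart here, and differences between a Cy3 and a Cy5 group hold them all. Epithelial genes rose more in Clusters 1+2 than in Cluster 1 in 22 of 47 cases and less in 2 (camera adjusted p = 6.93e-18, correlation-adjusted p = 0.00586), and more than in Cluster 2 in 19 cases and less in 1 (camera adjusted p = 1.25e-15, correlation-adjusted p = 0.00549). Cholesterol synthesis genes were higher in Clusters 1+2 than in Cluster 1 in 22 of 25 cases (correlation-adjusted p = 0.00534) and than in Cluster 2 in 24 (correlation-adjusted p = 0.00105). Reported miR-200 targets were lower in Clusters 1+2 than in Cluster 1 in 16 of 53 cases and higher in 4 (correlation-adjusted p = 0.0251), and lower than in Cluster 2 in 13 of 52 and higher in 4 (correlation-adjusted p = 0.026). Interferon-stimulated genes were higher in Cluster 1 than in Cluster 2 in 13 of 34 cases (camera adjusted p = 2.87e-36, correlation-adjusted p = 0.0744). That difference depended on the control. With Cluster 1 taken against the other Puro vector its mean fell from 0.659 to 0.19, with 4 higher and 2 lower (camera adjusted p = 0.0127, correlation-adjusted p = 0.789). With the spread scaled between arrays, slopes lay between 0.771 and 1.13. Clusters 1+2 then exceeded Cluster 1 in 9 epithelial genes and fell below it in 2, exceeded it in 10 cholesterol synthesis genes, and were lower in 7 reported targets and higher in 1. None of these 3 lists was called there with an estimated correlation (correlation-adjusted p = 0.45, 0.183 and 0.45). Against Cluster 2, of the same dye and slides, 6 epithelial genes were higher and 1 lower (correlation-adjusted p = 0.0185), 14 cholesterol synthesis genes higher (correlation-adjusted p = 0.00307) and 3 reported targets lower (correlation-adjusted p = 0.0494). Against the miR-200 mean, CDH1 was lower for 27 epithelial genes and higher for 2 (correlation-adjusted p = 0.0046), lower for 23 of 25 cholesterol synthesis genes (correlation-adjusted p = 0.00192) and higher for 20 cell cycle genes and lower for 1 (correlation-adjusted p = 0.00338). Scaled spread gave correlation-adjusted p of 0.0702, 0.0108 and 0.0702 for these 3 lists. With CDH1 taken against the other Puro vector the cell cycle mean fell from 0.335 to 0.173, with 10 genes higher and none lower (correlation-adjusted p = 0.0146). The epithelial mean was then -0.659 beside -0.648 and that of cholesterol synthesis genes -1.04 beside -1.14. The Cdh1 effect differed between Clusters 1+2 and Cluster 1 (adjusted p = 6.71e-05) and between Clusters 1+2 and Cluster 2 (adjusted p = 0.00804). Cluster 1 less Cluster 2 was at -0.73, which missed the threshold (adjusted p = 0.0529), passed it with the slide as a block (adjusted p = 0.00589) and turned to 0.23 under scaled spread (adjusted p = 0.799). Under scaled spread the differences of Clusters 1+2 from Cluster 1 and from Cluster 2 were 0.42 (adjusted p = 0.485) and 0.65 (adjusted p = 0.621), and with the processed signals 0.03 (adjusted p = 0.985) and 0.51 (adjusted p = 0.786), so neither call held there. Counts and single genes stand in the closing section.

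The 2 Puro vector controls, alike by their labels and lying on slides 4 and 3, were compared to see how far control lines differ. Lsr was 1.35 higher (SE 0.121, adjusted p = 2.18e-05), Perp 1.23 higher (SE 0.0695, adjusted p = 6.75e-07) and Samsn1 1.21 higher (SE 0.0901, adjusted p = 5.27e-06) in the control of Cluster 1 than in that of CDH1. Emilin2 (-2.52, SE 0.105, adjusted p = 6.07e-08), Hp, the acute phase protein haptoglobin (-2.11, SE 0.215, adjusted p = 9.71e-05), and Cbr2 (-1.90, SE 0.0674, adjusted p = 2.05e-08) were lower. Fn1 was at -0.91 (adjusted p = 0.000126) and Zeb2 at -0.36 (adjusted p = 0.00819). For Cdh1 no size can be given, since the control of CDH1 was not above background on either array. Interferon-stimulated genes were lower in 17 of 34 cases and higher in none, with a mean of -0.469 (camera adjusted p = 1.53e-22, correlation-adjusted p = 0.0658). Other lists lay apart too, by mean log2 ratio in the control of Cluster 1 and of CDH1. NF-kB genes were at -0.0208 and 0.269, unfolded protein response genes at -0.406 and -0.139, and collagens at -1.32 and -1.05. Cell cycle genes were the other way, at 0.466 and 0.306, and epithelial genes lay close, at -0.126 and -0.138. In all 1903 of 18980 genes were called, 920 higher and 983 lower (1052 and 559 under median centring), 10 and 67 of them at least 2-fold, and slide and control line cannot be told apart here. The count was 1116 without replicate B of the control of CDH1, and 1092 and 1154 without replicate A and B of that of Cluster 1.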

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

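The settings with the other Puro vector as control of Cluster 1 or CDH1, the tests of the CDH1 control, both the share of its changes kept against the other Puro vector and the comparison of slides, and that of the cholesterol genes against the other Puro vector were chosen only after the result was seen.

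The results given first are differences between effects, each tested in limma as the difference itself at an adjusted p under 0.05. Where a control lay at background on both arrays, a difference has no defined size; this holds for Serpinb5, Crb3, Kcnk1, Epha4 and Esrp1 below, and for Cdh1 where CDH1 is compared. Dye, slides, reference signal and spread of the ratios differ between Cluster 1 or CDH1 and the other groups. Between Cluster 1 and Cluster 2 the effects of 505 genes differed (328 more positive in Cluster 1, 177 less; 158 and 837 under median centring). Rtp4 (2.09), Il33 (2.04) and Mgp (1.94) were more positive in Cluster 1 (0.96, 1.68 and 0.61 with the other Puro vector for Cluster 1), and Kctd12b (-2.40), Hs3st1 (-2.10) and Serpinb5 (-1.89) more positive in Cluster 2. For Serpinb5 neither size nor direction is settled, since its controls were dim and the processed signals and the matrix gave 0.94 (adjusted p = 0.754). The Hs3st1 effect is likewise without a size in Cluster 1, where both arrays were dim. The count was 211 without Hygro vector replicate B, 308 without Cluster 2 replicate B, 194 without Cluster 1 replicate A, and 263 and 292 without replicates A and B of the control of Cluster 1. Without Cluster 2 replicate A the balance turned to 210 and 289.

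Clusters 1+2 differed from Cluster 1 in 2955 genes (1361 more positive and 1594 less; 146 and 452 with the processed signals, 655 and 1295 under median centring). Scaled spread gave 447 and 674. Kctd12b (3.83), Crb3 (3.51) and Kcnk1 (3.097) led one way, and Mgp (-4.28), Adgrg1 (-3.26) and Il33 (-3.10) the other. Cdh1 (1.65), Epcam (1.84) and Esrp1 (1.47) were more positive in Clusters 1+2. By contrast Zeb2 (-1.71), Sec23a (-1.18), Igfbp4 (-0.87) and Snai1 (-0.51) were less. The calls of Cdh1, Epcam, Igfbp4 and Snai1 ended under scaled spread (0.421, 0.907, -0.666 and -0.369, lowest adjusted p = 0.107) and with the processed signals (lowest adjusted p = 0.191).

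Clusters 1+2 differed from Cluster 2 in 1178 genes (550 more positive and 628 less; 18 and 117 with the processed signals, 307 and 2069 under median centring, 720 and 521 without Hygro vector replicate A). Here Epha4 (2.37), Abcg2 (2.21) and Kcnk1 (2.21) stood against Mmp3 (-3.04), Adgrg1 (-2.91) and Slc14a1 (-2.45). Differences were 0.92 for Cdh1, 1.56 for Epcam, 1.29 for Esrp1, -1.33 for Zeb2, -0.84 for Igfbp4 and -0.57 for Snai1. Those of Cdh1, Epcam, Igfbp4 and Snai1 were not called under scaled spread (0.653, 1.24, -0.641 and -0.443, lowest adjusted p = 0.337) or with the processed signals.

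CDH1 differed from the mean of the 3 miR-200 overexpressions in 3301 genes (1662 more positive and 1639 less; 2148 and 1025 under median centring, 1024 and 1160, 2184 in all, without CDH1 replicate B, and 927 and 998 with CDH1 taken against the other Puro vector). Id2 (2.53), Il11 (2.18) and Mmp3 (2.11) were more positive in CDH1, and Krt7 (-3.55), Gsn (-3.34) and C3 (-3.28) less; with that control they lay at 1.65, 1.20, 1.47, -3.49, -2.06 and -1.70. The Cdh1 value of -1.39 is no measured size, since its control for CDH1 was at background, and its sign turned with the processed signals and the matrix (0.27, adjusted p = 0.676). Further differences were 0.88 for Zeb2, 0.57 for Sec23a, 0.43 for Tinagl1, -1.04 for Fn1, -2.54 for Epcam and -0.42 for Esrp1. With the other control for CDH1 those of Sec23a (0.433), Tinagl1 (0.149) and Fn1 (-0.132) were not called.

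The 3898 genes called in the mean of the miR-200 overexpressions were set against other splits of the arrays within each experiment. Of 100 splits, the real one included and drawn from 108, only 1 gave as many genes; the highest of the others gave 3197 and their median was 1. Splits that mix overexpression and control arrays of an experiment widen the spread within groups. Any lasting difference between lines would therefore set the real split apart too. The test thus speaks only against arrays that are interchangeable within each experiment, and cannot tell an effect of the constructs from other differences between lines. Each of the 3 comparisons sets arrays against controls of the same slides, so slides cancel, while differences between lines stay open.

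Changes in Cluster 1 and in CDH1 ran opposite ways, with a correlation of -0.385 across genes and 712 genes called in opposite directions. It lay between -0.158 and -0.421 in 13 other settings. A difference between arrays in the spread of their ratios is argued against as the whole cause, since after regressing both changes on each gene's mean ratio the correlation was still -0.294. The 2 Puro control lines lying apart stays open: with controls exchanged the correlation was -0.124, between the bounds set for and against it, and exchanging them also mixes slides. A biological difference between Cluster 1 and CDH1 was not tested apart from these and stays open as well.

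The changes in CDH1 depended on the control. Over the 2750 genes called against its own Puro vector, the median share of the change kept against the other Puro vector was 0.292. In simulated data with no change, the 2750 genes of lowest p kept 0.49, since both changes share the CDH1 arrays. Choosing genes by their call can lower the share too. Genes chosen on 1 repeat of CDH1 and its control were therefore measured on the other repeat, where the median share was 0.258 (1464 genes, quartiles -0.00521 and 0.512) and 0.264 (966 genes, quartiles 0.0561 and 0.514). Such shares go with the 2 Puro controls standing apart. Simulated data with equal controls gave 0.898 for genes called and measured on all arrays, beside 0.292 here. In simulated data with no change the changes against both controls correlated at 0.486 across genes, from the shared CDH1 arrays alone, beside 0.498 here. Agreement across all genes therefore says little, although 284 genes were called the same way against both and the simulation called 0 in both. Whether line or slide separates the controls cannot be told apart: slides 1 and 2, the only pair sharing groups, differed at least 2-fold in 4 genes, the Puro controls on slides 4 and 3 in 77, but no such group links slides 3 and 4. A candidate explanation is a drift of the control line, which these arrays cannot test.

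Cholesterol synthesis genes fell in CDH1 and rose with each miR-200 construct. In Cluster 1 against the other Puro vector the rise kept its camera call but lost it with an estimated correlation. A control of CDH1 that stands apart is argued against as the whole cause, since the mean of the list was -0.412 against the other Puro vector beside -0.513 against its own. Unequal spread of the ratios is argued against too, since after regression on the mean ratio the list kept -0.496. All 4 arrays of the comparison with its own control lie on slide 3, so slides cancel there. An effect of CDH1 and a difference of the CDH1 line from both control lines were not tested apart and stay open.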

How the results depend on the processing

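Removing marked spots before the background step was chosen only after the result with outlier spots kept was seen, and the other Puro vector as control of CDH1 or of Cluster 1 was also chosen after seeing the data. Array weights, a mean-variance trend, the mean of all probes and a replicate block left all 10 counts of genes within 1.5 times. The miR-200 seed site test and its variants were not run. Low signal limits genes near background, such as Cdh1, whose Puro control for CDH1 lay at background. Its difference in CDH1, no measured size, was 0.61 here (range 0.51 to 2.53), 2.53 with the processed signals and 0.56 with outlier spots kept. For the values below the cause was not tested, except that leaving arrays out of a fit lowers its degrees of freedom. Counts follow the order of the report: each single cluster, both clusters, CDH1, the miR-200 mean, the 4 differences as in the closing text on them (Cluster 1 less Cluster 2 first), and the Puro controls.

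The processed signals and, identically, the series matrix gave 568, 89, 1588, 1621, 1513, 23, 598, 135, 1693 and 959 genes. Outlier spots kept gave 195, 82, 2699, 1255, 1738, 30, 1029, 285, 1399 and 539. Offset 10 gave 262 for Cluster 2 and 574 for Clusters 1+2 less Cluster 2. Median centring gave 2272 for Cluster 2 and 995, 1950 and 2376 for the first 3 differences. Scaled spread gave 75 for Cluster 2, 1853 for Clusters 1+2, 2217 for the miR-200 mean, and 1121 and 121 for Clusters 1+2 less Cluster 1 and less Cluster 2. The sample channel alone gave 209, 2698, 1822 and 2386 for Cluster 2, Clusters 1+2, CDH1 and the mean, and 1714 and 465 for the same differences. For Cluster 1 less Cluster 2, no filter gave 308, the filter on all 16 arrays 997 and the slide as a block 845. Only the arrays compared gave 60 for Cluster 2, 3116 for Clusters 1+2, and 202 and 702 for the differences of Cluster 2 from Cluster 1 and from Clusters 1+2. With the slide as a block Cluster 2 had 784 genes, and against the other Puro vector CDH1 had 458. CDH1 less the miR-200 mean had 1925 with that control for CDH1. The other Puro vector for Cluster 1 left the 5 counts that hold Cluster 1 within 1.5 times (1628 for Cluster 1).

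Leaving out 1 array at a time gave, in the same order, 675 to 978, 231 to 805, 3292 to 4143, 1542 to 2064, 3206 to 3801, 194 to 647, 2067 to 2953, 807 to 1241, 2184 to 3349 and 1092 to 1429 genes, a lone array being assumed to vary like the other groups. At an adjusted p under 0.01 the genes shared in the same direction numbered 101 (Cluster 1 and Cluster 2), 327 (Cluster 1 and Clusters 1+2), 32 (Cluster 1 and CDH1), 224 (Cluster 2 and Clusters 1+2), 57 (Cluster 2 and CDH1) and 432 (Clusters 1+2 and CDH1), as stricter calls shorten every list. Directions reversed for Serpinb5 in Cluster 1 less Cluster 2 (0.94) and Cdh1 in CDH1 less the miR-200 mean (0.27) with the processed signals and the matrix, for Hp in CDH1 against the other control (0.0748), for Fn1 in Cluster 1 (-0.768), Cluster 1 less Cluster 2 (-0.584) and Clusters 1+2 less Cluster 1 (0.553) and for matrix proteases (-0.138) and NF-kB genes (-0.151) in Cluster 1 with the other control for Cluster 1, and for 3 lists called only in the other setting: COPII genes (0.222) and cell cycle genes (0.266) in Cluster 2 under median centring, and endothelial markers in Cluster 1 with the sample channel alone (0.262). Means of further lists turned sign without a call there, as given beside those lists. Calls of named genes over all comparisons stayed as they were for 215 values with the processed signals, while 39 ended and 2 reversed. With outlier spots kept 208 stayed and 48 ended, and under scaled spread 227 stayed and 27 ended. Of 125 list tests, 83 did so with an estimated correlation; the other 42 were no longer called.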

Other observations

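The comparisons with the other Puro vector, of probes, of repeat letters and of signs across comparisons, and the setting with outlier spots kept, were chosen only after the result was seen.

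Further gene lists were tested in Cluster 1, and those called lost the call with an estimated correlation. TGF-beta response genes counted 8 higher and 4 lower of 27, with Ccn2 at 0.92, Ltbp2 at 0.90 and Id3 at -0.72 (camera adjusted p = 0.0368, correlation-adjusted p = 0.578). Of 24 p53 target genes 7 rose, among them Perp (1.94), also on the epithelial list, Gadd45a (0.70) and Fas (0.54; camera adjusted p = 2.65e-07, correlation-adjusted p = 0.116). Actin cytoskeleton and YAP-responsive genes rose in 7 of 35 cases, including Tpm2 (0.96; camera adjusted p = 0.00891, correlation-adjusted p = 0.417). NF-kB and inflammatory genes had 7 higher and 3 lower of 27, with Saa3 at 1.04 (camera adjusted p = 0.0406, correlation-adjusted p = 0.362). Against the other Puro vector that list turned, with 2 higher and 7 lower (mean -0.151, camera adjusted p = 0.000354, correlation-adjusted p = 0.394). COPII and early secretory genes rose in 4 of 36 cases, with Surf4 at 0.37 and Bet1 at 0.34 (camera adjusted p = 0.0301, correlation-adjusted p = 0.191). Matrix proteases and inhibitors (4 higher, 1 lower of 30; camera adjusted p = 0.187), hypoxia and glycolysis genes (4 higher, 2 lower of 31, with Aldoc at 1.29; camera adjusted p = 0.334), Wnt/beta-catenin response genes (1 and 1 of 21; camera adjusted p = 0.822), Notch pathway genes (1 higher of 18; camera adjusted p = 0.329), immediate early and heat shock genes (1 higher, 5 lower of 18; camera adjusted p = 0.181) and the Sec23a-dependent secreted factors (1 lower of 2; camera adjusted p = 0.0764) were not called as lists. Against the other Puro vector p53 target genes had 6 higher and 1 lower (correlation-adjusted p = 0.094), TGF-beta response genes 5 and 4, actin cytoskeleton and YAP-responsive genes 6 and 2, COPII genes 3 and 4, hypoxia genes 1 and 6 and matrix proteases 3 and 6 (mean -0.138, camera adjusted p = 0.00267, correlation-adjusted p = 0.559).

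In Cluster 2, TGF-beta response genes rose in 6 of 27 cases (10 adjusted over the list alone), with Pmepa1 at 0.87 and Inhba at 0.52 (camera adjusted p = 0.000183, correlation-adjusted p = 0.441). Unfolded protein response genes (2 higher of 28; camera adjusted p = 0.033, correlation-adjusted p = 0.441), p53 target genes (1 higher of 24; camera adjusted p = 0.00744, correlation-adjusted p = 0.48) and actin cytoskeleton and YAP-responsive genes (3 higher and 1 lower of 35, with Ankrd1 at 0.68; camera adjusted p = 0.0095, correlation-adjusted p = 0.48) had positive means that turned to -0.013, -0.0779 and -0.00336 with outlier spots kept. Jag1, a Notch ligand, rose by 1.07 while Notch1 was lower at -0.65, and the Notch list was not called (camera adjusted p = 0.846). Not called either were hypoxia and glycolysis genes (none of 30; camera adjusted p = 0.174), matrix proteases (1 higher, 1 lower; camera adjusted p = 0.502), NF-kB genes (2 higher, 2 lower of 26; camera adjusted p = 0.846), Wnt genes (1 lower; camera adjusted p = 0.337), COPII genes (1 lower; camera adjusted p = 0.337), immediate early genes (1 higher, 2 lower; camera adjusted p = 0.477) and the Sec23a-dependent factors (none of 2; camera adjusted p = 0.502).

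In Clusters 1+2 several groups split. TGF-beta response genes had 9 higher and 11 lower of 27, with Ccn2 at 1.92 and Id2 at -2.19 (camera adjusted p = 0.968). Actin cytoskeleton and YAP-responsive genes had 12 higher and 3 lower of 35, with Ankrd1 at 1.46 and Ccn1 at 1.15 (camera adjusted p = 0.00724, correlation-adjusted p = 0.506). Notch1 was at -2.35 and Jag1 at 1.83, with 4 higher and 3 lower of 18 Notch genes (camera adjusted p = 0.968). Hypoxia and glycolysis genes had 13 lower and 3 higher of 30, with Bnip3 at -0.78 and Kdm3a at -0.70 (camera adjusted p = 0.0254, correlation-adjusted p = 0.432). Wnt/beta-catenin response genes had 8 lower and 3 higher of 21, with Tnfrsf19 at -1.32, Notum at -1.03 and Myc at 0.75 (camera adjusted p = 0.132). NF-kB genes had 9 higher and 6 lower of 27, with Ptgs2 at 1.49 and Vcam1 at -1.84 (camera adjusted p = 0.839). p53 target genes had 7 higher and 4 lower of 24, with Perp at 2.89 and Cdkn1a at -0.90 (camera adjusted p = 0.00122, correlation-adjusted p = 0.263). Unfolded protein response genes had 8 higher and 1 lower of 28 (camera adjusted p = 0.14), matrix proteases 6 and 6 of 30, with Mmp10 at -1.16 and Htra1 at 1.14 (camera adjusted p = 0.289), and immediate early genes 4 and 3 of 17, with Egr3 at -1.17 and Jun at -0.81 (camera adjusted p = 0.698).

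In CDH1, matrix proteases and inhibitors fell in 7 of 30 cases and rose in 1, with Adam8 at -2.14 and Pcolce at -0.77 (camera adjusted p = 5.72e-05, correlation-adjusted p = 0.181). COPII and early secretory genes had 10 lower and 2 higher of 36, with Mcfd2 at -0.82 and Kdelr3 at -0.61 (camera adjusted p = 0.0122, correlation-adjusted p = 0.181), and their mean of -0.115 turned to 0.0668 under median centring. Immediate early and heat shock genes had 5 lower and 2 higher of 18, with Hspb1 at -1.03 (camera adjusted p = 0.0352, correlation-adjusted p = 0.666), and a mean of -0.14 that turned to 0.0298 under median centring. TGF-beta response genes (3 higher with Id2 at 1.55, 7 lower with Ltbp2 at -1.41; camera adjusted p = 0.192), p53 target genes (2 higher, 5 lower; camera adjusted p = 0.816), Wnt genes (4 and 4; camera adjusted p = 0.962), Notch genes (2 lower; camera adjusted p = 0.286), actin cytoskeleton and YAP-responsive genes (1 higher, 4 lower; camera adjusted p = 0.962), adherens junction genes (3 higher, 1 lower; camera adjusted p = 0.962) and the Sec23a-dependent factors (none; camera adjusted p = 0.962) were not called as lists. Against the other control 2 matrix proteases were lower and 1 higher, 1 COPII gene was lower and 2 immediate early genes were lower.

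Markers of other cell types were counted in each comparison, in the order Cluster 1, Cluster 2, Clusters 1+2 and CDH1. Among 20 leukocyte markers Cd14 was called in Cluster 1 (1.38) and in CDH1 (-0.97), with camera adjusted p = 0.00351 in Cluster 1 (correlation-adjusted p = 0.624) and 0.645, 0.839 and 0.0937 in the others. Of 14 endothelial markers Flt1, also a reported miR-200 target, was lower in all 3 miR-200 comparisons and higher in CDH1 (0.56), with camera adjusted p of 0.444, 0.46, 0.038 and 0.812, the called value becoming correlation-adjusted p = 0.854. These markers depended on the control: against the other Puro vector 4 were higher and none lower in CDH1 (mean 0.301, camera adjusted p = 1.71e-09, correlation-adjusted p = 0.0792), where Flt1 was at 0.06 (adjusted p = 0.787). In Cluster 1 5 were lower and none higher (mean -0.292, camera adjusted p = 9.87e-06, correlation-adjusted p = 0.0608). Mammary basal and myoepithelial markers had no called member of 12 in either single cluster, Col17a1 (-0.97), Mylk (-0.81) and Krt14 (0.46) in Clusters 1+2 and 1 lower in CDH1 (camera adjusted p of 0.444, 0.846, 0.839 and 0.962). Of 12 luminal and milk markers 2 were higher and 1 lower in either single cluster, 3 and 2 in Clusters 1+2, and 1 and 1 in CDH1. Krt18 was at 1.26, 1.04 and 1.56 and Krt8 at 0.81, 0.65 and 0.85 in the miR-200 comparisons, and Krt19 at 1.73 in Clusters 1+2. Lower were Areg in Cluster 1 (-0.72), Csn3 in Cluster 2 (-0.62) and Clusters 1+2 (-1.53), Gata3 in Clusters 1+2 (-0.78), and Krt8 in CDH1 (-0.55), with Gata3 at 0.28 there (camera adjusted p of 0.117, 0.104, 0.354 and 0.962). Among 17 muscle and adipocyte markers Tnnt2 (0.73, 0.95, 1.05 and 0.33) was called in all 4 comparisons, and Fabp4 in Cluster 2 (-0.59), Clusters 1+2 (-1.86) and CDH1 (0.43) (camera adjusted p of 0.144, 0.427, 0.839 and 0.557).

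Several genes called in all 3 miR-200 comparisons moved the opposite way in CDH1, examples chosen after their values were seen: C3 (-2.05), Cbr2 (-1.35), Cav1 (-1.30), Gsn (-1.16), Celsr1 (-1.16) and Sphk1 (-1.13). Against the other Puro vector only C3 of these was called lower (-0.477), Cbr2 was higher (0.542, adjusted p = 0.00108), as in the miR-200 comparisons, and Cav1 (0.282), Gsn (0.121), Celsr1 (-0.38) and Sphk1 (-0.448) were not called. With the own control Spryd7 (1.23) and Itgb7 (-0.91) changed the same way in CDH1 as in the miR-200 comparisons, though neither was called against the other (0.292 and 0.0453). Cluster 1 against the other Puro vector had Cbr2 (-0.314), Cav1 (-1.16) and Celsr1 (-0.366) lower. Of the 4699 genes called in Clusters 1+2, 61.8% had the same sign in Cluster 1, 87.0% in Cluster 2 and 58.4% in CDH1. Among called genes with several probes, probes differed in sign for 204 of 698 in Cluster 1, 39 of 202 in Cluster 2, 405 of 1980 in Clusters 1+2 and 366 of 1293 in CDH1; with each probe at an unadjusted p under 0.05 the numbers were 15, 5, 53 and 34. For Cluster 2 and Clusters 1+2 the repeat letter is also the slide. Deviations of repeat A in an overexpression and its control correlated at -0.0141 in Cluster 1, 0.276 in Cluster 2, 0.333 in Clusters 1+2 and 0.013 in CDH1.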
